A study of Mus musculus with 4 samples.

How the data were processed

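The samples are 4 libraries of RAW264.7 mouse macrophage cells treated with LPS for 12 hours, 2 with a nonspecific control shRNA and 2 with an shRNA against Mettl3. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cDNA was primed on the poly(A) tail of total RNA, extended to full length by template switching and amplified by PCR, fragmented, circularised and sequenced as single-end reads of 50 bases on a BGISEQ-500. This kind of library does not mark the strand of the RNA, so reads of a gene and of an antisense partner cannot be told apart. The reads carry no molecular identifiers, so standard errors cover counting error and the spread between libraries after PCR.

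The authors deposited a table of 14435 genes with Entrez identifiers and symbols and, for each library, an estimated count, an FPKM and a TPM value. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the mouse build mm9 were used, with no role or order given. The gene annotation, filters and strand setting are not given in the sources used here. The estimated counts are the authors' unnormalized expected counts per the file headers and the values, which are not whole for 1808 genes (12.5%), as when reads are divided between related genes. The FPKM values were deposited as fragments scaled to gene length and library size, per the file headers. The TPM values were deposited as transcript shares that sum to 1000000 in each library, within rounding. The table has 0 columns of other samples. 21 symbols had been turned into dates and were restored through their Entrez identifiers. 14335 identifiers matched a RefSeq gene annotation on GRCm38, and 100 did not, and 14216 were protein-coding. This annotation gave the restored symbols, while transcript length and sequence came from GENCODE M21, also on GRCm38. Both are of a later build than mm9, so no coordinates are printed. The table has 0 mitochondrially encoded genes, and the list of them was not analysed here.

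The totals of the estimated counts were 17142599 and 17193639 for the control libraries and 16342313 and 16767622 for the knockdown libraries, and the 10 most abundant genes took between 7.46% and 8.12%. Counts were rounded to whole numbers. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fitting) on the group, with genes kept by filterByExpr on the group (minimum count 10, minimum total count 15) and TMM factors of 0.97 and 0.966 for the controls and 1.03 and 1.04 for the knockdown libraries. It left 11035 genes in the test and 3400 below the filter. P-values were adjusted by Benjamini-Hochberg over the tested genes and called below 0.05. The common biological coefficient of variation was 0.068, with 2 residual degrees of freedom and a median prior of 9.1. Standard errors were computed as the size of the log2 fold change over the square root of the F statistic. CPM values are scaled by the TMM factors.

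Before the replicates were combined they were compared. Chi-square over its degrees of freedom, across genes, was 11.5 between the controls and 4.15 between the knockdown libraries, so neither pair agrees within sampling noise, and it lay between 61.1 and 79.8 for pairs across groups. The correlation of log CPM across genes, which are not independent replicates, was 0.993 in the controls and 0.995 in the knockdown group.

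33 gene lists were written before the data were examined, as were the main design, the rule for named genes and all alternatives but 1. 29 of the lists had at least 5 tested members and were tested with camera (limma 3.58.1). It was run on log CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over these lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera rests on the 2 residual degrees of freedom, so it has little power to call a list here. The lists were m6A writers other than Mettl3, m6A readers and erasers, NOD1 and NOD2 signalling, the TLR4 receptor complex and adaptors, NF-kB subunits and inhibitors, MAPK kinases and phosphatases, cytokines, chemokines, LPS-induced enzymes and effectors, interferon-stimulated genes, nucleic acid sensors, inflammasome and pyroptosis, macrophage identity, alternative activation, MHC class I presentation, MHC class II presentation, osteoclast markers, scavenging, phagocytosis and lipid efflux, cholesterol biosynthesis, glycolysis and HIF1 targets, the amino acid and ER stress response, p53 targets, S phase and replication, G2 and mitosis, JAK-STAT feedback, mitochondrially encoded genes, ribosomal proteins, oxidative phosphorylation and immediate early genes, and markers of fibroblasts, lymphocytes, dendritic cells, and neutrophils and mast cells.

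The rule for named genes takes Mettl3, Mettl4, Nod1, Nod2 and Ripk2. It adds the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, with a mean of at least 10 CPM in the higher group and predicted genes with no symbol left out. It adds up to 3 called members in each direction from each list, or the 2 most abundant members where none was called. This gave 162 genes, of which the text names a part, and genes named outside the rule are said to have been chosen after their values were seen.

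The alternatives were DESeq2 1.42.0, limma-voom, edgeR without robust fitting, RLE and upper quartile factors, library size alone, no filter on low counts, a mean CPM of at least 5, a replicate block, each library left out in turn, and limma on log2 of FPKM or TPM plus 1 (FPKM also plus 0.1) for genes at 1 or more in at least 2 libraries. On these log2 scales the pseudocount understates the changes of low genes. A GC correction was added after the data were examined. It takes a smooth curve of each library's level on transcript GC content as an offset. GC content, transcript length and DRACH motifs, the sequence context of m6A, came from the transcript with the longest coding sequence of each gene, for 10852 of the tested genes (98.3%), with motifs counted as exposed when more than 100 bases from an exon junction. Intervals are 95% bootstrap intervals from 2000 resamples. These steps used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and the figures matplotlib 3.10.9.

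The steps were tested on simulated counts for this comparison with 10953 genes passing the filter and 200 genes changed before it. The main test recovered 76 of 99 genes changed 1.5-fold (76.8%) and 90 of 100 changed 2-fold (90%), with 21 calls among 10754 unchanged genes. DESeq2 recovered 64.6% and 85%, and limma-voom 74.7% and 90%. EdgeR with 1 library left out recovered 70% and 88%, on 10986 genes, with 36 calls among 10786 unchanged genes. It thus gave more false calls than the main test while recovering fewer changed genes, so calls in the leave-one-out fits are less reliable. A simulated GC trend gave 1217 calls among 10745 unchanged genes when left in and 9 among 10572 when removed. The camera step called a list lowered 1.5-fold and 0 of the 23 lists that shared no member with it, over 10948 genes. Genes were simulated independently of one another, so this check does not cover lists whose members vary together between libraries. The motif step gave a partial rho of 0.009 with no dependence, 0.014 with GC dependence alone and 0.298 with motif dependence, over 10355 genes. That dependence was simulated on the part of motif number that length, GC content and level leave unexplained. It does not cover a dependence shared with them.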

Results

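RNA was measured by sequencing in RAW264.7 cells, an established mouse macrophage line, after 12 hours of treatment with bacterial lipopolysaccharide (LPS), a ligand of the receptor TLR4. 2 libraries came from cells given a nonspecific control shRNA and 2 from cells given an shRNA against Mettl3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. All 4 libraries were treated with LPS, so the comparison is knockdown against control under LPS, and the effect of LPS itself was not measured. The total estimated counts were 17142599 and 17193639 in the control libraries and 16342313 and 16767622 in the knockdown libraries. Between 12810 and 13323 genes had at least 1 count. The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Values below are counts scaled to library size (CPM) and log2 fold changes, knockdown over control, with their standard errors (SE). Each group has n = 2, and a gene was called at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11035 tested genes.

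The targeted gene was lower in both knockdown libraries. Mettl3 (Entrez gene 56335) had estimated counts of 514 and 496 in the control libraries and 194 and 195 in the knockdown libraries, or 30.9 and 29.9 CPM against 11.5 and 11.2 CPM. Its log2 fold change was -1.42 (SE 0.10, adjusted p = 1.58e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Some Mettl3 counts were not whole numbers, as happens when the counting divides reads between genes, and the value carries that uncertainty. The label of knockdown replicate 2 names METTL4 in one field, while its title and the design of the series name METTL3. Mettl4 (Entrez gene 76781) had 439 and 404 counts in the controls and 410 and 432 in the knockdown libraries, a log2 fold change of -0.04 (SE 0.09) that was not called. Its sign turned with library size as the scaling (0.05), with FPKM (0.14) and TPM (0.20), and without control replicate 1 (0.00), and it was not called in any of these fits. The table gives no coordinates, and none are given here, because the reference at hand is of another genome build than the one in the submitters' notes.

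**Figure D1:**
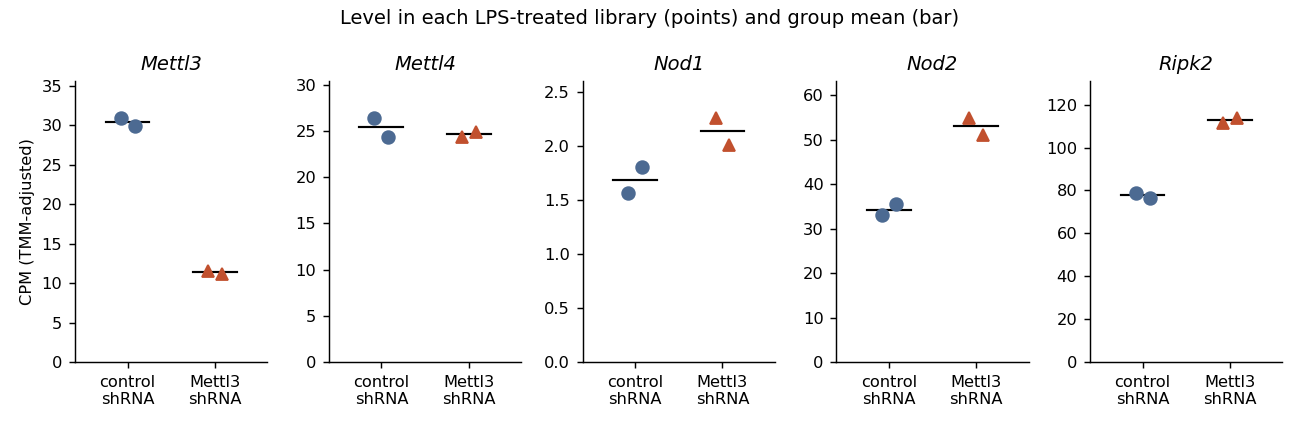
Level of 5 genes in each LPS-treated library, in CPM scaled by TMM factors, with control shRNA libraries as blue circles, Mettl3 shRNA libraries as orange triangles and group means as bars. Mettl3 lay at 30.9 and 29.9 CPM in the controls and at 11.5 and 11.2 CPM after knockdown, while Nod1 stayed between 1.57 and 2.26 CPM in all 4 libraries.

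The title of the series places NOD1 signalling between METTL3 and the LPS response. Nod1 (Entrez gene 107607), a cytosolic sensor of bacterial peptidoglycan, had 26 and 30 counts in the controls against 38 and 35 in the knockdown libraries. Its log2 fold change of 0.34 (SE 0.26) was not called (adjusted p = 0.323 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and a change of this size was not detectable at these counts. The related sensor Nod2 (Entrez gene 257632) rose from 34.3 to 53.1 CPM, with 549 and 591 counts against 924 and 890 (log2 fold change 0.63, SE 0.08). Ripk2 (Entrez gene 192656), the kinase that both sensors recruit, rose from 77.8 to 113 CPM, with 1312 and 1273 counts against 1872 and 1981 (log2 fold change 0.53, SE 0.07). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 1.21e-04 for Nod2 and 1.03e-04 for Ripk2. Over the list of NOD1 and NOD2 signalling, 10 of 26 tested members rose and 0 fell, and adjusted over the list alone the counts were the same, 10 and 0. Besides Nod2 and Ripk2 the members that rose included the ubiquitin ligase Birc2 (0.66), Slc15a3, a transporter of peptidoglycan fragments (0.58) and Tnfaip3 (0.44), which encodes A20, an inhibitor of NF-kB. The counts were 10 and 2 without control replicate 1 and 9 and 2 without control replicate 2, and 1 member fell with no filter on low counts and with the GC trend removed. The list as a set was not called by camera (adjusted p = 0.15).

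A large share of the genes differed between the knockdown and control libraries. An effect of Mettl3 loss cannot be told apart here from other differences between the cell populations that carry each shRNA. Of 11035 tested genes, 2360 rose and 2466 fell, 43.7% in all. Counts of list members are to be read against these shares. The change was at least 1 on the log2 scale for 463 genes that rose and 524 that fell. The groups did not overlap for 73.4% of tested genes, where chance gives 33.3% for 2 libraries against 2. A test against a 1.5-fold change called 952 genes, of which 415 rose and 537 fell. Without knockdown replicate 1 the count of calls was 3095. The split of directions depends on the scaling. With TMM 48.9% of the calls rose, against 64.1% with library size alone, 63.4% with the authors' FPKM and 70.1% with their TPM. These scalings move the median log2 fold change of all genes from 0.01 to 0.11, 0.09 and 0.14, so the changes below are relative to the TMM scale.

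Among called genes with an established symbol, a mean of at least 10 CPM in the higher group and groups that did not overlap, the largest fall was in Mmp9, the secreted gelatinase, from 825 to 34.9 CPM, a log2 fold change of -4.56 (SE 0.18). Collagen genes were among the largest falls as well, with Col5a3 at -3.96 (SE 0.18) and Col18a1 at -2.65 (SE 0.12). Ccr1, a chemokine receptor, fell by 2.83 on the log2 scale, the C-type lectin receptor gene Clec4n by 2.99 and Id1, an inhibitor of basic helix-loop-helix transcription factors, by 2.75. The other genes in the 12 largest falls were Serinc2, Plpp3, Msantd3, Rasgrp4, Rbfox1 and Dmwd, with log2 fold changes between -3.09 and -2.61. The largest rise was in Neo1, the receptor neogenin, from 7.14 to 97.7 CPM (log2 fold change 3.77, SE 0.09). It was followed by C1qtnf6 and Antxr1, both at 3.20. P2rx7, the ATP-gated channel, rose from 44.3 to 249 CPM (2.49, SE 0.08), and Cd86, a ligand that costimulates T cells, from 5.69 to 33.4 CPM (2.55, SE 0.12). Rcsd1, Glrp1, Rhox2d, Acsf2, Hoxc4 and Ccdc57 rose by between 2.49 and 2.88. Ifit1bl1, an interferon-inducible gene (2.99, SE 0.61), completes the 12 largest rises. Its adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0421, and its call was lost without knockdown replicate 1 (0.316), without knockdown replicate 2 (0.287) and with no filter on low counts (0.0894).

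Most genes of macrophage identity fell. 20 of 31 tested members fell and 2 rose, and adjusted over the list alone 21 fell and 2 rose. The median log2 fold change was -0.49, and the list was called by camera with the preset correlation (adjusted p = 9.58e-05), though not with an estimated correlation (adjusted p = 0.793). Lyz1, a lysozyme gene that shares reads with related genes, fell by 2.02 on the log2 scale. Adgre1, which encodes the macrophage surface protein F4/80, fell from 246 to 71.0 CPM (-1.79, SE 0.08) and Cebpa, a transcription factor of the myeloid lineage, by 1.67. Csf1r, the receptor for the growth factor CSF1, fell by 1.04, and Spi1, which encodes the transcription factor PU.1, had a log2 fold change of -0.06 (SE 0.07) that was not called. Csf1r and Spi1 were chosen after their values were seen. Fcer1g, a signalling chain of Fc receptors, rose (0.49), as did the receptor gene Fcgr2b (0.51), which lost its call without knockdown replicate 1 and with the GC trend removed, leaving 1 that rose. Without control replicate 1, with FPKM and with TPM 4 rose.

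Most osteoclast markers, which RAW264.7 cells can express because the line can form osteoclasts, fell as well. Of 16 tested members 9 fell and 2 rose, with the same counts adjusted over the list alone, and the median was -0.64. The camera test called the list (adjusted p = 8.6e-04, and adjusted p = 0.793 with an estimated correlation). Mmp9 is in this list. Car2, a carbonic anhydrase, fell by 2.52 on the log2 scale and Fos, a subunit of the AP-1 transcription factor, by 1.84, while Tnfrsf11a, which encodes the receptor RANK, rose (0.36). Only 1 member rose without control replicate 1, with either knockdown library left out, in DESeq2 and in edgeR without robust fitting. In the list of scavenging, phagocytosis and lipid efflux, 9 of 18 members fell and 2 rose, or 11 and 2 adjusted over the list alone, with a median of -0.41 (camera adjusted p = 0.0118, and adjusted p = 0.793 with an estimated correlation). Lpl, the lipoprotein lipase, fell from 1441 to 388 CPM, Gas6, a ligand of the receptors Axl and Mertk, from 29.7 to 8.57 CPM, and Abca1, a cholesterol exporter, from 107 to 41.7 CPM. Apoe rose from 3.52 to 6.23 CPM. Without control replicate 1 the number of members that rose was 4, and with a mean CPM of at least 5 it was 1.

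MHC class II presentation had 5 of 6 tested members fall and 0 rise, with the same counts adjusted over the list alone. Its median was -0.87 (camera adjusted p = 0.00607, and adjusted p = 0.793 with an estimated correlation). The list has 12 members. The class II chain genes H2-Aa, H2-Ab1 and H2-Eb1 and the regulator gene Ciita were absent or below the filter, so they were not tested. Cd74, the invariant chain, fell from 785 to 355 CPM (-1.15, SE 0.08) and the protease gene Ctss from 939 to 495 CPM (-0.92, SE 0.09). The number that fell was 3 without control replicate 1 and 2 without knockdown replicate 1. DESeq2 and the removal of the GC trend also left 3, and with no filter on low counts the list was no longer called (adjusted p = 0.213). In the list of alternative activation, 8 of 13 tested members fell and 3 rose, or 9 and 3 adjusted over the list alone. The list has 22 members, and Arg1, Retnla, Chil3, Cd163 and Pparg were among those absent or below the filter. The median was -0.83 (camera adjusted p = 0.0383, and adjusted p = 0.857 with an estimated correlation). Tgm2, a transglutaminase, fell by 1.09 and the scavenger receptor gene Stab1 by 1.07, while Clec10a, a lectin, rose (1.88). The call on this list was lost without knockdown replicate 2 (adjusted p = 0.0683) and with the GC trend removed (0.0631). Only 1 member rose with control replicate 2 or knockdown replicate 1 left out, in DESeq2, with FPKM and with a mean CPM of at least 5.

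More of the enzymes and effectors that LPS induces fell than rose. Of 30 tested members 14 fell and 6 rose, or 15 and 6 adjusted over the list alone, with a median of -0.34 (camera adjusted p = 0.0118, and adjusted p = 0.857 with an estimated correlation). Besides Mmp9, Slc7a2, an arginine transporter, fell by 2.39 and Slc7a11, the cystine transporter, from 479 to 155 CPM (-1.63, SE 0.07). Cd86 and Edn1, which encodes endothelin (1.25), rose. Nos2, the inducible nitric oxide synthase, chosen after its values were seen, had a log2 fold change of 0.85 (SE 0.34) and an adjusted p of 0.173 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The log2 fold change was 1.27 without control replicate 1 and 0.52 without control replicate 2, so the controls differed in this gene. Fits without a control library take their spread from the knockdown libraries alone. Limma-voom (adjusted p = 0.00799), edgeR without robust fitting, FPKM and TPM called Nos2.

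The cytokines moved in both directions. Of 22 tested members 8 rose and 4 fell, or 9 and 5 adjusted over the list alone, with a median of 0.18 that camera did not call (adjusted p = 0.531). That median was 0.05 without control replicate 1, 0.34 without control replicate 2 and 0.07 without knockdown replicate 1. Il6 rose from 7.29 to 30.6 CPM (log2 fold change 2.07, SE 0.22). Il1f6, an IL-36 gene, rose from 0.903 to 2.70 CPM (1.57, SE 0.33). Csf2, which encodes GM-CSF, fell from 4.70 to 0.822 CPM (-2.51, SE 0.47), and Il33 (-1.73) and Tgfb1 (-0.63) fell too. 3 further cytokines were chosen after their values were seen. Tnf rose slightly, from 1054 to 1275 CPM (0.27, SE 0.07), and its adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment went from 0.0114 to 0.148 without knockdown replicate 1. Il1b (-0.66, SE 0.45) and Il1a (-1.28, SE 0.38) were not called. They were -1.07 and -1.63 without control replicate 1, and Il1a was -0.83 without control replicate 2. The spread in these 2 fits comes from the knockdown libraries alone. Il1a was called in DESeq2, limma-voom and edgeR without robust fitting, and with FPKM and TPM. Without control replicate 1 the list had 8 members that rose and 7 that fell, without knockdown replicate 1 it had 5 and 3, and with a mean CPM of at least 5 it had 5 and 2. Among 15 chemokines 5 rose and 5 fell, with the same counts adjusted over the list alone. Their median was 0.02, their mean -0.13, and camera's direction was down (adjusted p = 0.871). Ccl7, a monocyte attractant, rose from 144 to 245 CPM and Cxcl14 fell from 12.4 to 2.22 CPM, while Ccl22 fell by 1.06. The chemokine median was 0.34 without control replicate 2 (6 rose, 3 fell), -0.11 without knockdown replicate 1 (2 rose, 3 fell) and 0.21 without knockdown replicate 2.

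The pathways between TLR4 and these outputs also had members that moved either way. In the list of the TLR4 receptor complex and its adaptors, 6 of 20 rose and 5 fell, or 8 and 5 adjusted over the list alone (median 0.06, camera adjusted p = 0.574). The adaptor genes Tirap (0.81) and Ticam2 (0.65) and the ubiquitin ligase gene Peli1 (0.74) rose. Cd14, the LPS co-receptor, fell from 4015 to 2875 CPM (-0.48, SE 0.08). The median was 0.00 without control replicate 2, and the number that fell was 3 without knockdown replicate 2 and 2 with TPM. Among 14 NF-kB subunits and inhibitors 6 rose and 3 fell, or 6 and 4 adjusted over the list alone (median 0.05, camera adjusted p = 0.574). Nfkbiz, which encodes a nuclear protein of the IkB family (0.79), and Tnfaip3 rose, and Nfkbid and Bcl3, which encode other nuclear members of that family, fell by 0.39 each. For MAPK kinases and phosphatases, 6 of 23 rose and 8 fell, or 6 and 9 adjusted over the list alone. The median of this list was 0.06, its mean -0.05, and camera's direction was down (adjusted p = 0.686). The median was between -0.08 and -0.02 in all 4 fits that left out 1 library. The phosphatase genes Dusp2 (1.18) and Dusp6 (1.12) rose, and Dusp1 (-1.08), Map2k3 (-0.75) and Mapk3 (-0.68) fell. JAK-STAT feedback had 7 of 19 members fall and 1 rise, or 7 and 2 adjusted over the list alone (median -0.13, camera adjusted p = 0.193). Cish, an inhibitor of cytokine receptor signalling, fell from 5.93 to 0.467 CPM (-3.64, SE 0.53), Ptpn6 fell by 0.65 and Tyk2, a Janus kinase, rose (0.63). In this list 1 member rose and 4 fell in DESeq2, and 4 rose and 5 fell with FPKM and TPM. Its median was -0.10 without control replicate 1, -0.15 without knockdown replicate 2 and 0.00 with TPM. 3 rose in limma-voom and edgeR without robust fitting, and 2 without control replicate 2, with library size alone, upper quartile factors and a mean CPM of at least 5.

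Interferon-stimulated genes had 8 of 46 tested members rise and 0 fall, or 4 and 0 adjusted over the list alone, with a median of 0.55. That share of rises is no higher than the share over all tested genes, 2360 of 11035. Camera called the list with the preset correlation (adjusted p = 1.25e-04) but not with an estimated correlation (adjusted p = 0.857). Iigp1, an interferon-induced GTPase, rose from 0.753 to 4.84 CPM (2.67, SE 0.36). Isg15 (0.74, SE 0.20) and Ifit1 (0.94, SE 0.52), chosen after their values were seen, were not called. They were 1.02 and 1.56 without control replicate 1, and Isg15 was 0.50 without control replicate 2. The spread in these 2 fits comes from the knockdown libraries alone. Limma-voom, edgeR without robust fitting, FPKM and TPM called both, and Isg15 was also called in DESeq2, with every other scaling and with a mean CPM of at least 5. The control libraries themselves differed in this list, with a median of 0.64 on the log2 scale between replicates 1 and 2, against 0.25 between the knockdown libraries. Leaving out control replicate 1 gave 34 members that rose and a median of 0.97. Leaving out control replicate 2 gave 14 that rose and 4 that fell with a median of 0.31, and leaving out knockdown replicate 1 gave 3 that rose. The number that rose was 4 with no filter on low counts, 13 in DESeq2, 26 in edgeR without robust fitting, 28 in limma-voom and with FPKM, and 30 with TPM. Nucleic acid sensors followed the same libraries, with a difference of 0.42 between the controls. 5 of 18 rose and 2 fell, or 4 and 2 adjusted over the list alone (median 0.27, camera adjusted p = 0.227). That median was 0.45 without control replicate 1 and 0.06 without control replicate 2. Aim2, a sensor of cytosolic DNA, rose (0.51) and Tlr8, a sensor of single-stranded RNA, fell from 9.94 to 2.64 CPM (-1.91, SE 0.21). Without control replicate 1 the counts were 11 and 2 and camera called the list (adjusted p = 0.0224), without control replicate 2 they were 3 and 5, and with either knockdown library left out 3 and 1. With TPM 8 rose, and 1 member fell in DESeq2, with library size alone, upper quartile factors, FPKM or TPM, and with the GC trend removed.

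Genes of the inflammasome and pyroptosis had 8 of 20 members rise and 2 fall, or 10 and 3 adjusted over the list alone (median 0.15, camera adjusted p = 0.168). That median was 0.29 without control replicate 1. P2rx7 is in this list, and Casp4 (1.11, SE 0.13), a sensor of cytosolic LPS, and Casp1 (0.87, SE 0.09), the protease that matures interleukin 1 beta, rose as well. P2rx4 fell by 0.43. Without control replicate 2 the counts were 7 and 6, and 1 member fell with either knockdown library left out, with library size alone, FPKM and TPM. For MHC class I presentation 5 of 21 rose and 1 fell, with the same counts adjusted over the list alone (median 0.17, camera adjusted p = 0.163), and the controls differed by 0.23 in this list. H2-M3 rose from 12.0 to 22.0 CPM and Psme1, a proteasome activator subunit, from 127 to 174 CPM. Without control replicate 1 the counts were 10 and 1 and camera called the list (adjusted p = 0.0224). It also called it without knockdown replicate 2 (0.0435), while the median was 0.03 without knockdown replicate 1 and 0.04 without control replicate 2. The number that rose was 8 with library size alone, upper quartile factors or FPKM, and 9 with TPM, and 0 fell with each of these, with either knockdown library left out and with the GC trend removed, and 2 without control replicate 2.

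Most genes of the amino acid and ER stress response rose. 16 of 27 rose and 3 fell, with the same counts adjusted over the list alone, and the median was 0.36 (camera adjusted p = 0.00607, and adjusted p = 0.857 with an estimated correlation). Hspa5, the ER chaperone BiP, rose from 1542 to 4056 CPM (1.40, SE 0.08), its co-chaperone Dnajb9 from 23.9 to 58.6 CPM and Trib3 from 7.29 to 16.8 CPM. Slc7a11 is also in this list and fell, as did Slc3a2 (-0.90) and Nupr1 (-0.82). The median was 0.23 without control replicate 1. Glycolytic genes and targets of HIF1 fell in 17 of 24 cases and rose in 1, or 18 and 1 adjusted over the list alone (median -0.34, camera adjusted p = 7.82e-04, and adjusted p = 0.857 with an estimated correlation). Aldoa, the aldolase, fell from 2746 to 1838 CPM (-0.58, SE 0.07), and Pfkfb3, which makes the activator of phosphofructokinase, fell by 0.64. The number that fell was 10 without knockdown replicate 1 and 11 with TPM. 0 rose in DESeq2 and with either knockdown library left out, and 2 with library size alone and TPM.

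Ribosomal protein genes had 26 of 51 members fall and 0 rise, or 28 and 0 adjusted over the list alone, with a median of -0.22 (camera adjusted p = 9.58e-05, and adjusted p = 0.857 with an estimated correlation). Rpsa fell from 3189 to 2243 CPM (-0.51, SE 0.06) and Rpl6 from 1560 to 1125 CPM (-0.47, SE 0.07). The count depended on the scaling and on the libraries. It was 11 with FPKM, 11 with library size alone and 7 with TPM, and 3 members rose with each of library size alone and TPM. Without knockdown replicate 1 it was 7 and without knockdown replicate 2 it was 10. 1 member rose without control replicate 2 and with the GC trend removed. Oxidative phosphorylation had 7 of 30 members rise and 5 fall, with the same counts adjusted over the list alone (median 0.04, camera adjusted p = 0.686). Cox5b (0.64) and Ndufs1 (0.42) rose and Atp5d fell by 0.37. The counts were 12 and 2 with library size alone and with TPM, 10 and 2 with FPKM, 4 and 2 without knockdown replicate 1, and 6 and 2 without knockdown replicate 2. Cholesterol biosynthesis was even, with 6 of 24 up and 6 down, also adjusted over the list alone (median -0.05, camera adjusted p = 0.778). Insig1 (0.76) rose, and Tm7sf2 (-1.34) and Pmvk (-0.79) fell. The counts were 5 and 12 without control replicate 1 and 10 and 6 without control replicate 2, and the median turned to 0.05 in the second case.

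Genes of G2 and mitosis had 12 of 32 members rise and 0 fall, with the same counts adjusted over the list alone, and the median was 0.42. Camera called the list (adjusted p = 7.82e-04) but not with an estimated correlation (adjusted p = 0.857). Plk1, a mitotic kinase, rose (0.87, SE 0.16) and Cdc25c, a phosphatase that starts mitosis, from 2.62 to 5.01 CPM (0.93, SE 0.23). The controls differed here too, by a median of -0.47 between replicates 1 and 2, against 0.02 in the knockdown group. The number that rose was 27 with a median of 0.65 without control replicate 2, 10 with a median of 0.18 without control replicate 1, where 1 fell, and 7 without knockdown replicate 1. It was 18 with library size alone and FPKM and 23 with TPM. For S phase and replication 8 of 33 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.12, camera adjusted p = 0.182). That median was 0.02 without control replicate 1 and 0.21 without control replicate 2. Mcm3 (0.48) and Mcm6 (0.44), subunits of the replicative helicase, rose. The counts were 5 and 4 without control replicate 1, 12 and 1 without control replicate 2, where camera called the list (adjusted p = 0.0188), 3 and 0 without knockdown replicate 1, and 5 and 0 with a median of 0.065 without knockdown replicate 2. The number that rose was 4 in DESeq2, 13 with library size alone and 15 with TPM, and 0 fell with each of these and with the GC trend removed. Among 19 targets of p53, 5 rose and 4 fell, with the same counts adjusted over the list alone (median 0.09, camera adjusted p = 0.574). Btg2 (1.17) and Bbc3 (0.92), which encodes the proapoptotic protein PUMA, rose. No target of p53 fell with library size alone, FPKM or TPM, or with either knockdown library left out, and 1 fell in DESeq2 and 2 with upper quartile factors. Among 22 immediate early genes 7 rose and 5 fell, or 8 and 6 adjusted over the list alone. Their median was 0.09, their mean -0.01 and camera's direction up (adjusted p = 0.706). Klf2 (1.10) rose with Btg2, and Myc (-0.87) fell with Fos. The counts were 4 and 4 with either knockdown library left out and in DESeq2, the number that rose was 11 with the GC trend removed, and the number that fell was 3 with a mean CPM of at least 5.

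Of 10 m6A writers other than Mettl3, 2 rose and 0 fell, with the same counts adjusted over the list alone (median 0.05, camera adjusted p = 0.531). They were Rbm15b (0.92, SE 0.11) and Rbm15 (0.43, SE 0.09), which guide the complex to its sites, and the count was 4 with library size alone and with TPM. The list median was 0.14 without control replicate 1 and 0.02 without control replicate 2. 1 fell without control replicate 2 and with the GC trend removed. Mettl14, the partner of Mettl3, had a log2 fold change of 0.22 (SE 0.13) and Wtap, a scaffold of the complex, one of 0.15 (SE 0.08) and neither was called. Both were named after their values were seen, and Wtap was called with library size alone (0.24), FPKM (0.28) and TPM (0.33), and Mettl14 with TPM (0.31). Of 13 readers and erasers 4 rose and 2 fell, with the same counts adjusted over the list alone (median 0.08, camera adjusted p = 0.582). The reader genes Igf2bp3 (1.73, SE 0.36) and Igf2bp2 (-0.67, SE 0.07) went in opposite directions. Without knockdown replicate 1 the counts were 1 and 1, and without control replicate 2 the median was 0.00. 1 fell without knockdown replicate 2, with library size alone, FPKM and TPM and with the GC trend removed.

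**Figure D2:**
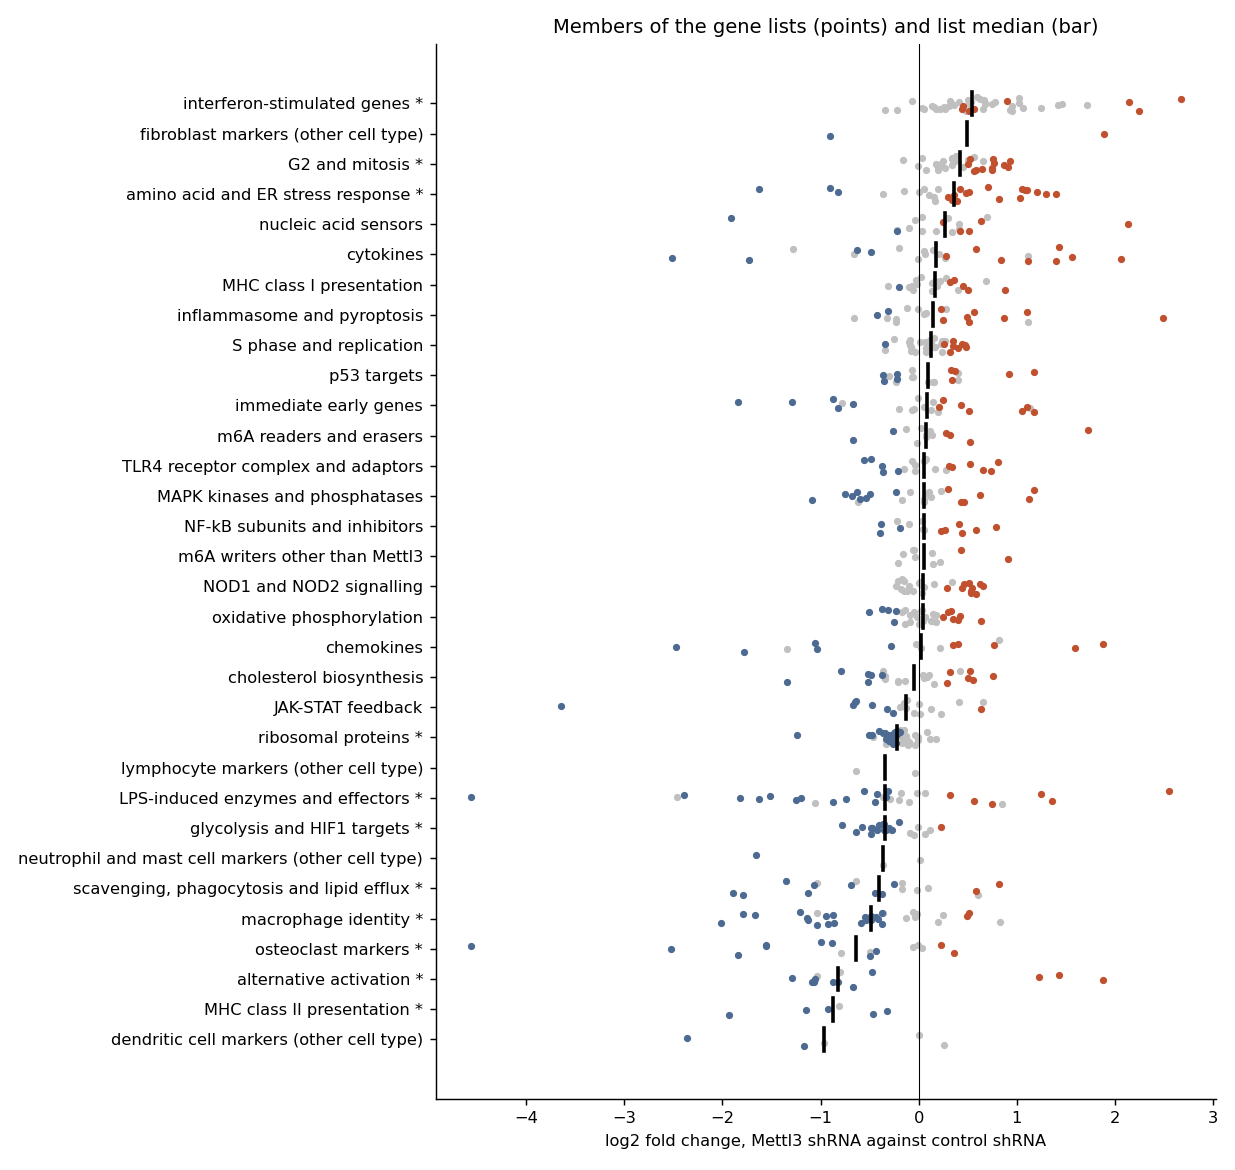
Log2 fold change of Mettl3 shRNA against control shRNA for each tested member of the gene lists (points, orange where it rose, blue where it fell, grey where it was not called), with the list median as a black bar. A star marks the 11 lists that camera called with the preset correlation, none of which it called with an estimated correlation, and the median of macrophage identity lies at -0.49.

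Few markers of other cell types passed the filter on low counts in this clonal line. Of 5 tested dendritic cell markers 0 rose and 2 fell, or 0 and 3 adjusted over the list alone (median -0.96, camera adjusted p = 0.147), and camera called the list without knockdown replicate 1 (0.0358). The number that fell was 1 without knockdown replicate 2, in DESeq2, with FPKM and with a mean CPM of at least 5. Itgax, an integrin chain also found on macrophages, fell from 26.5 to 5.15 CPM (-2.36, SE 0.18). Of 3 tested neutrophil and mast cell markers 1 fell, also adjusted over the list alone, Csf3r (-1.66, SE 0.19). Neither of the tested lymphocyte markers, Lck (-0.03) and Pax5 (-0.64), was called, nor was either one adjusted over the list alone. Lck and Pax5 changed sign without control replicate 1 (0.02 and 0.17), and Lck also without knockdown replicate 2 (0.12). 2 fibroblast markers were tested, and also adjusted over the list alone Pdgfrb rose (1.89, SE 0.46) and Acta2 fell by 0.90. The call on Pdgfrb was lost without knockdown replicate 1, that on Acta2 without control replicate 2 or knockdown replicate 2, and both in DESeq2. Knockdown replicate 1 held nearly all reads of 5 fibroblast matrix genes below the filter, which were chosen after their values were seen. It had 17 counts of Col1a1, 15 of Col1a2, 15 of Col3a1, 25 of Fn1 and 18 of Sparc, together 90 counts or 5.51 CPM, where knockdown replicate 2 had 1 count of Col1a1 and the other values were 0. They are the 5 genes of the whole table with at least 15 counts in that library and at most 2 in each other library. By the same cut the other 3 libraries had 0 such genes each. The cut of 15 equals the lowest count among the 5 genes, so it is not independent of them. With knockdown replicate 2 left out, 7 fibroblast markers passed the filter and 6 of them rose.

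**Figure D3:**
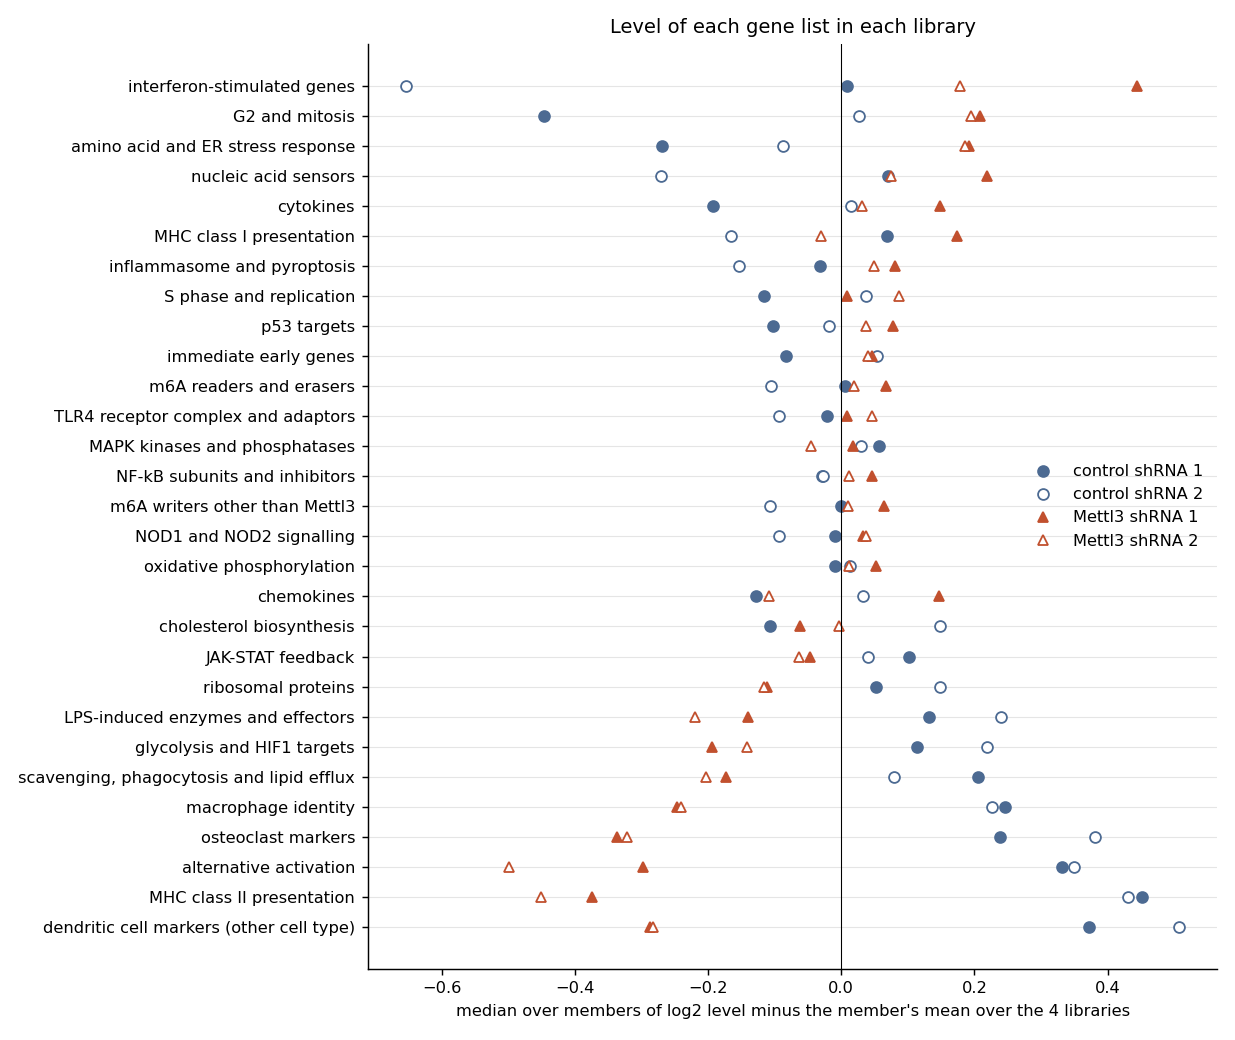
Level of each gene list in each library, as the median over its tested members of the log2 level minus that member's mean over the 4 libraries, with control libraries as circles and knockdown libraries as triangles (replicate 1 filled, replicate 2 open). The control libraries lie apart for the interferon-stimulated genes, at 0.01 and -0.65, and together for macrophage identity, at 0.25 and 0.23.

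Of 29 lists with at least 5 tested members, camera called 11 with its preset correlation of 0.01 and 0 with a correlation estimated per list. With the estimated correlation 1 list had an unadjusted p below 0.05, and the adjusted p of the 11 lists lay between 0.793 and 0.857. That version rests on 2 residual degrees of freedom, so the loss of calls cannot be credited to correlation between genes alone. Macrophage identity and osteoclast markers lost theirs although their estimated correlations, -0.031 and -0.058, were below the preset. The other called lists had estimates above it, up to 0.912 for interferon-stimulated genes and 0.832 for G2 and mitosis. The preset p-values of those 2 lists do not allow for so high a correlation. Fry, which asks whether a list moves on balance 1 way without comparing it with other genes, called macrophage identity (adjusted p = 0.00318), osteoclast markers (0.00318), MHC class II presentation (0.0401) and the scavenging list (0.0401). Values of genes with counts that were not whole, among them Lyz1, Rasgrp4, Ifit1 and Mettl3, are less certain than the rest.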

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

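The GC correction was chosen after seeing the data, and the other alternatives before. Between 952 and 5324 genes were called. The counts were 3475 with DESeq2, 4744 with limma-voom, 4773 without robust fitting, 4819 with RLE factors, 4821 with upper quartile factors, 5098 with library size alone, 4956 without the filter, 4144 with a mean CPM of at least 5, 4442 and 4394 with FPKM plus 1 and plus 0.1, 4857 with TPM, 4776 with the GC trend removed and 3233 at an adjusted p below 0.01. A test against a 1.5-fold change called 952, because it asks for a larger change. Leaving out 1 library gave 3095 to 5324 calls, and a group of 1 library is then assumed to vary like the other group. Among these settings only TPM (8) and the removal of the GC trend (1) turned the sign of any of the 4826 calls. The labels do not tie the replicate numbers of the groups and there are 2 pairs, so whether they pair the samples is unknown. In the interferon-stimulated genes replicate 1 lay above replicate 2 in both groups, by medians of 0.64 (controls) and 0.25 (knockdown). In G2 and mitosis the medians were -0.47 and 0.02, so the groups did not go together there. A pairing is not excluded by these values. The replicate differences of the groups correlate by 0.146 across genes, and the fit with the replicate block called 5116 genes, with 33 interferon-stimulated genes that rose. Mettl3 fell in every setting, by 1.21 (TPM) to 1.45 on the log2 scale (leave-one-out -1.40 to -1.45), and was called in each. Nod1 was never called (0.23 to 0.46, leave-one-out 0.23 to 0.44). It has no value under a mean CPM of at least 5, FPKM or TPM, where it is below the filter. Camera called 11 lists, 0 with an estimated correlation and fry 4, leave-one-out gave 12 to 13 and every other setting 10 or 11. DESeq2 and the fit without robust fitting give no log CPM of their own, so the list test was not run with them. Of the 160 called genes among those followed across settings, 123 were called in all settings that gave them a value. Over genes and settings, 157 values lost a call, 42 gained one and 2654, called or not, kept their direction and their side of the threshold. Over lists, 21 lost one, 5 gained one and 480, called or not, kept both. Among uncalled results, these signs turned and the cause was not tested. Lck was 0.061 with library size alone, 0.036 and 0.045 with FPKM plus 1 and plus 0.1, 0.085 with TPM, 0.028 with the GC trend removed and -0.201 to 0.12 in leave-one-out. Mettl4 was 0.051 with library size alone, 0.144 and 0.164 with FPKM, 0.202 with TPM and -0.108 to 0.004 in leave-one-out. Pax5 was -1.24 to 0.17 in leave-one-out. Spi1 was 0.034 with library size alone, 0.021 with both FPKM fits, 0.076 with TPM and 0.082 with the GC trend removed. The camera adjusted p of the chemokines, with the direction up, was 0.965 in limma-voom, 0.912 without the filter, 0.898 with a mean CPM of at least 5 and 0.563 to 0.843 in leave-one-out, up without control replicate 2 and without knockdown replicate 2. That of cholesterol biosynthesis was 0.974, up, with a mean CPM of at least 5 and 0.151 to 0.923 in leave-one-out, up without control replicate 2 and without knockdown replicate 1. That of the immediate early genes, down, was 0.968 with TPM and 0.738 by fry, and it was 0.568 to 0.858 in leave-one-out, down without control replicate 1. Depth limits the low genes most: 3400 of the 14435 genes were below the filter, and Nod1 had 26 to 38 counts per library.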

Other observations

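The tests of the Mettl3 shRNA RNA in a control library, of the share of macrophage cells, of shared reads and of GC content as the whole cause of the calls were chosen only after the result was seen, and the others before.

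The fold changes of all tested genes were set against transcript properties, across genes, which are not independent replicates. A rise of genes with more exposed m6A motifs, beyond other properties, would give a positive partial rho. With length, GC content and level removed the value was -0.017 (-0.035 to 0.003), which argues against such a rise. A dependence that motif number shares with length could be removed with it. Methylation was not measured, so an effect of m6A stays open. With these properties left in, rho was 0.064 (0.046 to 0.083). The median log2 fold change went from -0.027 in genes with the fewest exposed motifs to 0.052 in genes with the most. Transcript length gave a rho of 0.033 (0.015 to 0.052), which argues against a length bias. GC content gave -0.227 (-0.245 to -0.209), the size predicted for a GC bias. The median log2 fold change went from 0.12 in genes lowest in GC (median 42.7%) to -0.12 in genes highest in GC (57.6%). GC content as the whole cause is argued against, since 4107 of the 4752 calls with a GC value remained after the trend was removed. A GC bias may add to the fold changes, since the control libraries differed along GC as well (rho -0.315, against -0.094 between the knockdown libraries), and a change in GC-rich transcripts by the knockdown stays open and untested.

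The interferon-stimulated genes differed between the control libraries by a median of 0.643 over 46 members. After a trend on GC content and length was removed the difference was 0.65 (0.54 to 0.741), which argues against such a bias. Knockdown RNA in control replicate 1 would place the same share of it in all genes that rose. For 459 other genes that rose by at least 1 the median share was 0.0% (-0.4 to 0.4). The interferon-stimulated genes gave 57.9% (47.6 to 68.3). The selections differ, since the 459 genes had to be called, which favours genes whose controls agree. The interferon-stimulated genes needed only a knockdown mean above control replicate 2. The share near 0 is thus partly set by the selection, and it holds only for those 459 genes. A difference in the cultures, such as their exposure to LPS or interferon, could remain, and no biological explanation was tested because the labels give the controls the same treatment.

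Most macrophage identity genes fell after knockdown. A lower share of macrophage cells alone would lower every abundant member alike. Of the 24 members at 50 CPM or more in the controls 2 rose, Fcer1g (0.49) and Fcgr2b (0.51), and the largest fall was 2.02 on the log2 scale. Since 2360 of 11035 tested genes rose, these rises cannot exclude a lower share together with other changes. Fcgr2b lost its call without knockdown replicate 1 and with the GC trend removed, and Fcer1g was called in every setting. Reads shared with related genes are argued against by the 25 members with whole counts, whose median was -0.54 (-0.92 to -0.38). A response to the knockdown is a candidate explanation that stays open, as does a difference between the cell populations that carry each shRNA, and neither was tested.

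Counts of fibroblast matrix genes in knockdown replicate 1 were 17 for Col1a1, 15 for Col1a2, 15 for Col3a1, 25 for Fn1 and 18 for Sparc. Other fibroblast markers differed less between the knockdown libraries, with estimated counts in replicates 1 and 2 of 5.3 and 1.2 for Tagln, 20 and 15 for Pdgfrb, 36 and 30 for Acta2, 4 and 5 for Dcn and 1 and 2 for Col5a1, where the controls had 0 and 0, 5 and 4, 53 and 67, 0 and 1, and 1 and 3. The marker list was written before the data were examined, and the matrix genes were singled out from it after their values were seen.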
